A study of Mus musculus with 4 samples.

How the data were processed

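Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in cultured neural stem cells from female mouse embryos of embryonic day 14.5. Of the 4 libraries, 1 was a ChIP of Smchd1-deleted cells and 1 a ChIP of Smchd1-control cells, and each had 1 whole-cell-extract input library from the same kind of cells. Smchd1 was deleted with a retrovirus that carried Cre recombinase and puromycin resistance. Puromycin was added after 24 h and cells were collected on day 7, per the labels' protocols, while control cells were not transduced. Deletion, transduction and selection therefore cannot be told apart in these libraries. Groups were taken from the sample titles. Other fields disagree with them: the antibody field names the trimethyl mark of the same residue, the control ChIP is titled as homozygous floxed but has a deleted and a floxed allele in its genotype field, and the control input has a homozygous deleted genotype there. The series' design text describes RNA-seq of replicated lines, which was not analysed here.

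Reads were aligned to mm10 with Bowtie 0.12.9, and bcl2fastq was used, per the submitters' processing notes. The authors called narrow peaks with MACS2 2.1.0.20140616, separately for each ChIP library against its own input, at a q-value limit of 0.05, with down-sampling of the larger library and 1 tag kept per position, per the file headers. The deposited lists give for each peak its position, the pileup signal at its summit, −log10 p, −log10 q and the fold enrichment over the local background, all as the authors' MACS2 run wrote them. Fold enrichment is a ratio within 1 library to its own input and is not scaled between libraries. It was used here to describe, rank or filter peaks within a list, to recover the local input background of a peak, and, averaged over both lists without scaling, to match random gene lists. Per the file headers, tags were 80 bases long, 54194233 ChIP tags were left after filtering in deleted cells and 42277672 in control cells, and the input libraries kept 77101643 and 80601280 tags. Deeper ChIP sequencing lets a caller pass weaker peaks, so the length of a list moves with depth.

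Peaks on chromosomes 1 to 19 and X were compared. No interval carried more than 1 summit. A peak was shared when at least 1 base overlapped a peak of the other list, and otherwise list-only. The local input background of a peak was recovered from its pileup and fold enrichment, (pileup + 1) / fold − 1, and counted as above the genome-wide floor when it exceeded the lowest value of its list by over 2%. Shares have exact Clopper-Pearson 95% intervals, and ratios of peak numbers have intervals from the same binomial. The mean percentile shift of peaks shared 1 to 1 has a normal interval. They cover counting error only, and neighbouring peaks are not independent. With 1 library per group there is no replicate check, and no p-value between conditions is given. The gene table used was RefSeq on GRCm38.p6, whose primary chromosomes are those of mm10, with 34328 protein-coding and lncRNA genes. That table has no strand and no transcripts, so the planned test of peaks over transcription start sites became a test of peaks within 1 kb of either gene end. A gene counted here may therefore have its peak at its 3′ end, or at the promoter of a neighbour.

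Gene lists were fixed before the data were examined: 19 lists with 345 genes, of which 342 were in the gene table. For each list the number of members with a peak in the deleted list only, minus the number in the control list only, was set against 10000 random gene lists of the same size, matched on the mean gene-end enrichment of both lists. On simulated null lists this comparison placed 0.5% of 200 lists in its top 5%, so it rarely singles a list out. A missing peak counted as 0 in that mean, so genes in 1 list only were matched more often with other such genes. The matching thus fixes part of the outcome, and a high percentage does not show that a list is ordinary. Planted overlaps of 5000 and 2000 list-only peaks were recovered exactly, and a planted X ratio of 1.25 was recovered as 1.285. Gene clusters ran from the first to the last gene with 10 kb on each side. The boundary genes of the 15 clusters were written down after the files had been opened. The clusters were also compared with random autosomal windows of the same length, holding a gene end and the same number of control peaks (within 1 peak for the gamma protocadherins), a comparison added after their counts were seen. Of 300 random windows of a single length, far shorter than the longest cluster and each tested singly, 2% fell in the top 5%. Windows as long as that cluster and sums over clusters were not checked in this way. Random windows could overlap one another, the long ones most, so windows and draws are not independent. Small percentages of them are therefore approximate.

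Genes named in the text were chosen by rules fixed beforehand. They are Smchd1 and Xist, list members with a peak in 1 list only (at most 6 per list and direction), and in each direction the 10 genes with the most enriched gene-end peak, genome-wide and on X. The 5 most enriched list-only peaks over 5 kb from a gene end and the 5 most enriched genes of each list are also named. Gene models without an assigned symbol were counted but not named, and exceptions, such as examples of list members with peaks in both lists, were chosen after their values were seen and are marked in the text. Some genes that these rules select are not reported here. The alternatives were −log10 q of at least 5, fold enrichment of at least 5, lists of equal length, other overlap rules, gene-end windows of 500 and 2500 bases, and unmatched random lists. Thinning of the deleted library to the control depth, peaks anywhere in a gene, another matching, protein-coding genes alone and parts of X left out were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Allele-specific signal was not analysed here, since the peak lists do not separate the parental chromosomes.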

Results

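H3K27ac was profiled in 1 Smchd1-deleted and 1 Smchd1-control culture of female neural stem cells, each with its own input. Smchd1 encodes a chromatin protein of the inactive X chromosome that also acts at imprinted and protocadherin clusters. The cells carried a maternal X of strain 129 with a mutant Xist and a paternal Castaneus X. The authors' list held 91639 peaks for deleted cells and 63698 for control cells, of which 91557 and 63613 lay on chromosomes 1 to 19 and X. Filtered ChIP depth was 54194233 tags in deleted cells and 42277672 in control cells, a ratio of 1.28. There were no replicates in either group, so every difference below is between 2 libraries.

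Neural stem cell genes carried H3K27ac in both cultures. Of 24 such genes, 20 had a gene-end peak in both lists, among them, as examples chosen after their values were seen, Sox2 (fold enrichment 20.7 in the deleted list and 20.6 in the control list), Olig2 (20.7 and 22.4) and Nes (12.9 and 12.9). Nfia (5.04) and Lhx2 (3.50), transcription factors of neural progenitors, had a peak in the deleted list only, and Msi1 (3.23), an RNA-binding protein of neural stem cells, in the control list only. Markers of neurons, fibroblasts, microglia, pluripotent and endothelial cells were mostly without gene-end peaks. Such peaks in both lists were found at 2 of 18 neuron genes, 1 of 8 fibroblast genes, 1 of 7 microglia genes and 0 of 7 pluripotency genes. Of 6 endothelial genes, Pecam1 (3.23) had a peak, in the control list only, though with a window of 2500 bases it had one in both lists. Astrocyte genes had a peak in both lists at 5 of 8 members and oligodendrocyte genes at 3 of 9. Gfap (4.03) and Myrf (2.52, at a peak also next to Tmem258) were in the deleted list only. When a peak anywhere in the gene was counted, an alternative added after the data were seen, both lists had one at 4 of 7 microglia, 3 of 6 endothelial, 6 of 9 oligodendrocyte and 6 of 8 astrocyte genes, against 2 of 18 neuron and 1 of 8 fibroblast genes. On that count all 24 neural stem cell genes had a peak in both lists, Nfia, Lhx2 and Msi1 included. The most enriched genes of the deleted list were Kmt5b (27.03), Pou3f3 (24.3), the neighbours Slc4a1ap and Supt7l (24.0 each, at 1 shared locus) and Bahcc1 (23.3). Those of the control list were Kmt5b (25.8), Ccng2 (24.1), Sall3 (23.2), Olig2 (22.4) and Rexo4 (22.0).

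The targeted gene was examined first among single loci. Smchd1, at chromosome 17 from 71344489 to 71475366, had a gene-end peak in both lists (7.72 in deleted and 8.88 in control cells). A peak at a gene end does not test whether the floxed part was lost, so it does not check the labels. Xist, at X from 103460373 to 103483233, also had a peak in both lists (7.89 and 8.07).

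Most strongly acetylated regions were common to both cultures, and the lists parted among weak peaks. In the deleted list 46366 peaks, or 50.6% (95% interval 50.3 to 51.0), overlapped no control peak. In the control list 15444 peaks, or 24.3% (23.9 to 24.6), overlapped no deleted peak. The shared percentage rose from 22.1% in the least enriched of 10 equal groups of deleted peaks to 99.6% in the most enriched, and from 53.5% to 100% in the control list. Peaks within 1 kb of a gene end were list-only in 28.9% of deleted and 9.83% of control cases, against 58.4% and 30.9% elsewhere. At a fold enrichment of at least 5 the lists held 19156 and 18380 peaks, a ratio of 1.04 in place of 1.44. After thinning the deleted library to the control depth, a calculation added after the data were seen, the expected ratio was 1.32.

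The most enriched list-only peaks over 5 kb from any gene end lay mostly inside genes. The deleted list had 27996 such peaks and the control list 9550. In the deleted list the top 5 were at chromosome 9 from 37783619 to 37783855 (7.89, between genes), inside Zfhx3 at chromosome 8 from 108755319 to 108755681 (7.72), on X from 75734788 to 75735043 (7.50), inside Tef at chromosome 15 from 81811474 to 81811748 (7.22) and inside Zfp217 at chromosome 2 from 170130532 to 170131027 (7.05). In the control list they were at chromosome 12 from 68463709 to 68463987 (6.86, between genes), inside Chst3 at chromosome 10 from 60194116 to 60194391 (6.46), at chromosome 7 from 134234193 to 134234603 (6.25, between genes), inside Macrod1 and Flrt1 at chromosome 19 from 7099612 to 7099943 (6.25) and inside Ppp1r16b at chromosome 2 from 158723074 to 158723300 (6.05).

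The X chromosome, on which Smchd1 is best known to act, differed from the autosomes. X held 1074 deleted and 658 control peaks, a ratio of 1.63 (1.48 to 1.80), while the 19 autosomes ranged from 1.38 to 1.54 with a median of 1.43. X thus made up 1.17% (1.10 to 1.24) of deleted peaks and 1.03% (0.957 to 1.12) of control peaks, intervals that overlap. Only 80 of the control peaks on X, 12.2% (9.76 to 14.9), were absent from the deleted list, against 22.7% to 25.8% on the autosomes. Deleted-only peaks made up 49.6% (46.6 to 52.7) of deleted peaks on X, within the autosomal range of 48.5% to 54.5%. X peaks lay within 1 kb of a gene end more often, at 42.3% against 26.2% on the autosomes, and by position the deleted-only percentage was 31.3% against 28.8% near gene ends and 63.1% against 58.4% elsewhere. At a fold enrichment of at least 5 it was 40.9% on X and 21.7% to 31.0% on the autosomes. Away from gene ends the X ratio was 2.02, with autosomes from 1.46 to 1.66, and near gene ends it was 1.29, with autosomes from 1.14 to 1.27. The ratio rests in part on the far end of X: without the stretch from 160 to 180 Mb (203 deleted and 90 control peaks) it was 1.53, below the 1.54 of chromosome 12. In lists of equal length the ratio without that stretch was 1.16 (1.03 to 1.30), with an autosomal median of 0.978 and maximum of 1.09. At a fold enrichment of at least 5 the control-only percentage on X was 21.2%, and 18 autosomes lay below it.

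**Figure D1:**
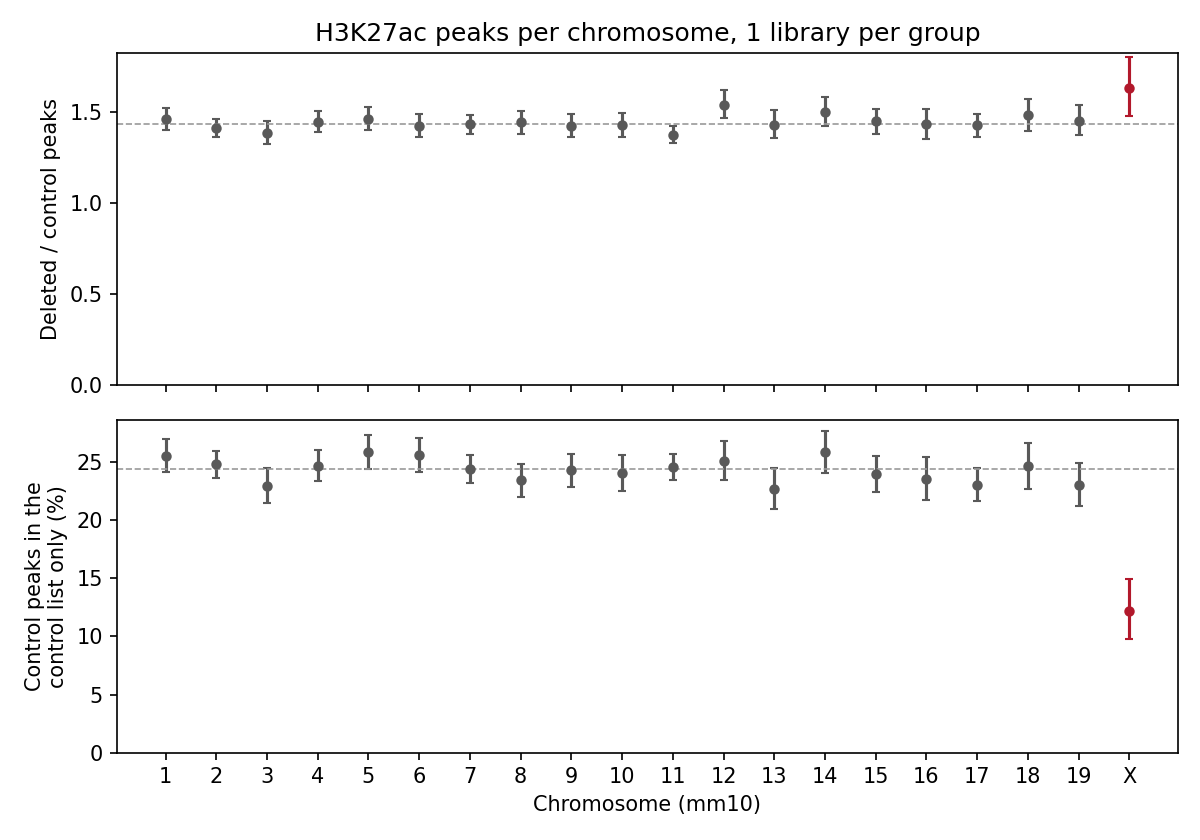
Ratio of deleted to control H3K27ac peaks (upper panel) and percentage of control peaks found in the control list only (lower panel) for each chromosome, as points with 95% counting intervals and the autosomal median as a dashed line. X has the highest ratio, 1.63, and the lowest control-only percentage, 12.2%.

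Within that stretch, peaks of deleted cells gathered between 166 and 167 Mb, a region singled out after its values were seen. It held 90 deleted and 25 control peaks, of which 69 and 0 were list-only. Of these, 64 deleted and 16 control peaks lay inside Gpm6b (X from 166238943 to 166389033), which encodes a membrane glycoprotein of neural cells. They covered 29.9 kb in the deleted and 7.27 kb in the control list, with highest fold enrichments of 9.91 and 6.66. Without this 1 Mb the X ratio was 1.55 (1.41 to 1.72), an interval that includes the autosomal median. In lists of equal length it was 1.17 (1.05 to 1.31) against an autosomal median of 0.978 and a maximum of 1.09, which that interval includes. The control-only percentage was 12.6% (10.1 to 15.5).

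Among X-linked genes with a gene-end peak in either list, 72 had it in the deleted list only, or 19.7% (15.7 to 24.1), against 14.1% (13.6 to 14.7) of autosomal genes. The control list alone had 10 X-linked genes, or 2.73% (1.32 to 4.97), against 3.10% of autosomal genes. Among protein-coding genes alone, a count added after the data were seen, both percentages were higher on X, with 16.2% (12.3 to 20.7) against an autosomal interval of 10.4% to 11.5% in the deleted list only and 3.17% (1.53 to 5.76) against 1.76% to 2.27%, which overlaps, in the control list only. The ratio of the 2 was 5.10 on X and 5.45 on the autosomes. The 10 most enriched deleted-only genes on X were Tmsb4x (7.22), Htatsf1 (5.83), Akap17b (5.21), Lrch2, Nexmif, Pgrmc1 and Plxna3 (4.70 each), Elk1 and Tceal9 (4.53 each) and Brcc3 (4.37). For Tmsb4x and Nexmif the peak did overlap a control peak that ended outside the 1 kb window. The peak of Brcc3 also lay next to Cmc4 and Mtcp1. The control-only genes on X were Hmgn5 (4.84), Chic1 (4.44), Mtmr1 (4.24), Rpgr (4.04), Zfp182 (3.63), Dgkk (3.60), Gab3 and Tro (3.43 each), and Drp2 and Zfp300 (3.03 each). Of 8 genes known to escape X inactivation, 6 had peaks in both lists, including the later chosen examples Ddx3x (14.6 and 12.6) and Kdm5c (10.8 and 12.4), and Utp14a (3.53) and the lncRNA 5530601H04Rik (4.03) had one in the deleted list only. In the X-inactivation centre 5 of 9 genes had peaks in both lists, and Chic1 in the control list only. None of the 14 reproductive homeobox genes on X had a peak.

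Across the genome 13271 genes had a gene-end peak in both lists, 2284 in the deleted list only and 496 in the control list only. Of 79 genes named for a peak in 1 list only, 34 had one in both lists when the window was 2500 bases. Among the 10 most enriched deleted-only genes were Supv3l1 (10.6), Ccdc112 and Eprs (10.2 each), Kcnv1 (9.74), Agbl3 (9.40), Fitm1 (9.07), Ss18 (8.90), Wfdc21 (8.83) and Nlgn1 (8.73). In 9 of these 10, all but Agbl3, the peak overlapped a control peak that missed the window, so they mark shifted peak edges and not list-only peaks. The peaks of Ccdc112, Fitm1 and Wfdc21 also lay next to Pggt1b, Psme1 and Heatr6. The most enriched control-only genes were Rab21 (8.47), Scaf4 (6.66), Mmp11 (6.46), Dse (6.25), Hsd17b1 (5.85), Nudt13, Prmt3 and Usp13 (5.25 each), and Cnn2 and Pkn3 (5.04 each), and in 6 of these 10 the peak overlapped a deleted peak. The peaks of Mmp11 and Hsd17b1 also lay next to Smarcb1 and Coasy. Ranked only among genes whose peak was itself list-only, a rule chosen after the values were seen, the deleted list was led by Agbl3 (9.40), Ptov1 (8.23), Ern1 (7.56), Camkv and Man2b2 (7.39 each), among others, and the control list by Nudt13 and Prmt3 (5.25 each). The peak of Camkv also lay next to Traip.

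Imprinted genes, another known class of Smchd1 targets, had 8 members with a gene-end peak in the deleted list only and 0 in the control list only, with 15 in both and 23 in neither. Those in the deleted list only were Igf2r (4.70), Snurf (4.20), Nnat (3.86), Zrsr1 (3.83), Zim1 (3.53), Ndn (3.36) and, named beyond the rule, Peg3 and Usp29, which share 1 peak (3.02). All 8 lie on autosomes. Beside the peak of Peg3 and Usp29, a peak of both lists (6.38 in the deleted and 5.65 in the control list) ended just outside the 1 kb window. With a window of 2500 bases, 5 imprinted genes were deleted only and 19 had a peak in both lists. Of random lists matched on mean enrichment, 5.81% had as high a net number, and over the settings and matchings run this percentage ranged from 0.76 to 86.2. When a peak anywhere in the gene was counted, 5 imprinted genes were deleted only and 2 control only. On that count 79.15% of matched and 52.28% of unmatched random lists were as high. Matched random lists averaged a net number of 4.40 and unmatched ones 2.40, since the matching favours genes in 1 list only. Of the unmatched lists 0.76% were as high. Random lists were drawn gene by gene, while many imprinted genes are neighbours, and the 8 members rest on 7 distinct peaks. These percentages may therefore be too small. The imprinted clusters held 146 deleted and 71 control peaks, with 90 and 14 list-only. In the Snrpn-Ndn region of chromosome 7 (59218750 to 62474510) there were 36 deleted and 13 control peaks, with 24 and 0 list-only, and at Peg13 on chromosome 15 there were 39 and 15. Igf2r had 12 and 4, Peg3 had 13 and 4, H19-Igf2 had 4 and 0, Kcnq1 had 40 and 33 and Peg10 had 2 and 2. The Dlk1-Dio3 region had 0 in both. Windows with the same control peak numbers had a median of 106 deleted peaks in sum (95% of draws from 85 to 131), and 0.13% of draws reached 146. That percentage was 0.07 in lists of equal length, 0.59 at −log10 q of at least 5, 9.07 at a fold enrichment of at least 5, and 27.4 without the Snrpn-Ndn and Peg13 regions. The windows behind the draws overlap one another, so the smallest of these percentages are approximate.

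**Figure D2:**
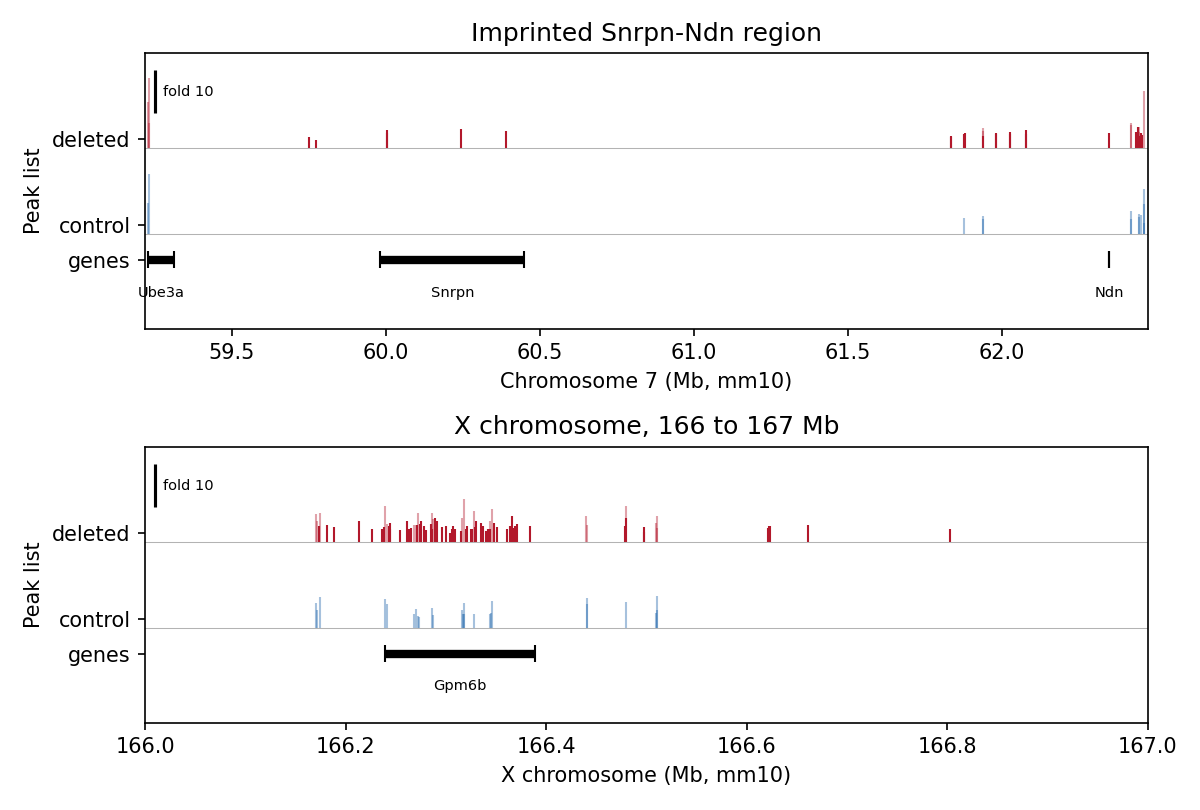
H3K27ac peaks as vertical lines, with height proportional to fold enrichment (scale bar, 10) and paler colour for shared peaks, along chromosome 7 at Snrpn-Ndn and along X from 166 to 167 Mb (positions in Mb, mm10). The deleted list has 36 and 90 peaks in these regions and the control list 13 and 25.

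Clustered protocadherins, cell-surface proteins of neurons encoded in tandem on chromosome 18, had gene-end peaks in both lists at 22 of 57 genes and in the deleted list only at Pcdhb17 (3.36) and Pcdhb19 (2.50). The 22 genes rest on 3 strongest peaks in each list, since 20 gamma genes end at a common point and share 1 peak there (7.26 in the deleted and 7.20 in the control list). The gamma cluster (37651775 to 37851873) held 36 deleted and 28 control peaks, with 13 and 0 list-only, the alpha cluster 3 and 4, and the beta cluster 2 and 0. Their sum of 41 was reached in 68.9% of draws of matched windows. The 4 Hox clusters, which pattern the body axis, had 0 peaks in both lists.

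Interferon-stimulated genes, part of the antiviral response, had gene-end peaks in the deleted list only at 5 of 17 members, in both lists at 6 and in the control list only at 0. The 5 were Irf7 (5.21), Ifih1 (4.87), Ifit1 (4.03, at a peak also next to Ifit1bl2), Isg15 (3.36) and Oas2 (2.57). As high a net number was found in 13.8% of random lists matched on mean enrichment, and in 0.43% to 46.6% over the settings and matchings run. The percentage was 4.55 when matched on the higher enrichment and 0.43 unmatched. Lists matched on the mean averaged a net number of 2.66 and unmatched ones 0.90, as that matching favours genes in 1 list only. Deleted cells had also been transduced with a retrovirus and control cells had not. Targets of p53 had peaks in both lists at 13 of 15 genes, with Mdm2 as an example chosen afterwards (8.90 and 8.27), and Fas (4.17) in the deleted list only. When a peak anywhere in the gene was counted, 14 of the 15 had one in both lists, Fas included. Germline genes had a peak only at Hormad1 (5.04, deleted list, next to Golph3l) among 14. Polycomb and Smchd1 partner genes had peaks in both lists at 17 of 19 genes and widely expressed reference genes at 14 of 15, with 0 in 1 list only. Over all deposited peaks none of the 19 lists had 5% or fewer of the random lists matched as planned at or above its net number, while in lists of equal length imprinted genes had 1.69%. With unmatched random lists 2 of the 19 had 5% or fewer, imprinted genes at 0.76% and interferon-stimulated genes at 0.43%. Neither count decides, since the planned matching fixes part of its outcome and unmatched lists ignore enrichment.

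**Figure D3:**
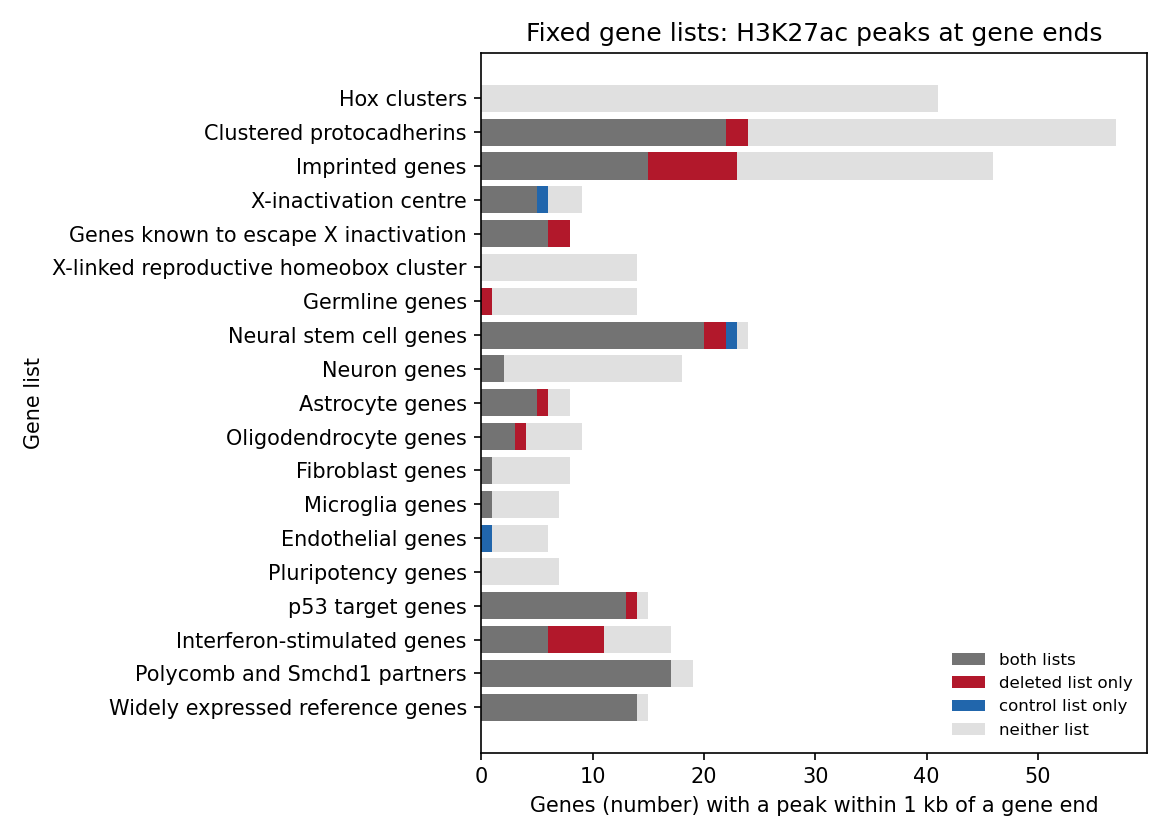
Number of genes in each fixed list (bars, horizontal axis) with an H3K27ac peak within 1 kb of a gene end in both lists, the deleted list only, the control list only or neither. Imprinted and interferon-stimulated genes have the most deleted-only members, 8 and 5.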

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

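Lists of equal length and the matching on mean enrichment were planned as alternatives or main tests. Their use against an explanation, and all other tests in this part, were chosen after the results they bear on had been seen.

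Outside the chromosomes compared, both lists held peaks on sequences used in no comparison. On Y, which female cells lack, there were 46 deleted and 35 control peaks, all between positions 90743351 and 90841827, around the start of the region that Y shares with X. On the unplaced sequence Un_JH584304 there were 28 deleted and 47 control peaks.

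Over all peaks X had the highest ratio of deleted to control peaks and the lowest control-only percentage. At a fold enrichment of at least 5 the ratio of X stayed highest. The control-only percentage of X was then 21.2%, with 18 autosomes below it. In lists of equal length the X ratio was 1.22 (1.10 to 1.35), an interval just above the highest autosome, 1.09. After thinning the ratio was 1.53, with an autosomal maximum of 1.41. Over all peaks, however, the interval of 1.48 to 1.80 holds the highest autosome, 1.54. Cutting the list also removes weak peaks, and deleted X peaks were stronger (median fold enrichment 3.76 against 3.53 on autosomes). Sequencing depth or list length as the whole source is therefore argued against only weakly. The 19.9% control-only peaks expected on X at autosomal rates, for the same enrichment, width and gene-end class, lies above the 12.2% observed. Loss of an X from every control cell is argued against by local input background. It exceeded its floor at 16.1% of control X peaks, within the autosomal range of 13.9% to 18.3%. After halving, only 0.43% of autosomal peaks would exceed the floor. Loss from part of the cells stays open. Shared X peaks stood a mean of 1.74 percentiles (−0.37 to 3.84) higher in the deleted list, an interval that holds 0. The highest autosomal mean was 1.06, on chromosome 17. In the deleted list 18.3% (16.1 to 20.8) of X peaks exceeded the floor, an interval that holds the autosomal maximum of 17.8%. Against 1 Mb around Gpm6b as the whole source, the ratio without it in lists of equal length was 1.17 (1.05 to 1.31). That interval lies above the autosomal median of 0.978 but holds the highest autosome, 1.09. The control-only percentage stayed at 12.6%, though over all peaks the ratio of 1.55 (1.41 to 1.72) has an interval that holds the autosomal median of 1.43. Deletion of Smchd1, transduction and selection remain open, as do loss of X from part of the cells and differences between single cultures or libraries. No value here separates them.

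The peaks at 166 to 167 Mb of X had the highest ratio, with 5 added to each count, among 1516 windows of 1 Mb with at least 20 peaks. The test set for sequencing depth or list length was whether the window lost its place in lists of equal length, where it held 60 deleted and 25 control peaks and ranked 2. That rank does not decide, since the window was picked for its ratio in the full lists, of which the shorter lists are parts. Local copy number gain cannot be told apart, since the recovered background is cut off at its floor: 3.33% (0.693 to 9.43) of the deleted peaks there had a local background of at least 1.5 times the floor, while the 16.0% (4.54 to 36.1) of control peaks above the floor, which a gain of that size would carry there, has an overlapping interval. A biological difference between the cultures, such as the deletion or a shift in cell state, is a hypothesis that was not tested further.

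Interferon-stimulated and imprinted genes had members with gene-end peaks in the deleted list only, and none in the control list only among all deposited peaks. Under the planned matching 13.8% of random lists were as high for interferon-stimulated and 5.81% for imprinted genes. That matching fixes part of the outcome: its random lists averaged net numbers of 2.66 and 4.40, against 0.90 and 2.40 unmatched. In lists of equal length, which bear directly on the longer deleted list, the percentages under the planned matching were 6.65% and 1.69%, over the matchings 0.46% to 6.65% and 0.84% to 1.69%, and the imprinted clusters held 103 deleted and 71 control peaks, reached by 0.07% of draws. For imprinted genes these values are low, but list length cannot be told apart for either list, since both were picked out of 19. Random lists also ignore that many imprinted genes are neighbours, so their percentages may be too small. Over all deposited peaks 27.4% of draws were as high without the Snrpn-Ndn and Peg13 regions. With a peak anywhere in the gene, 79.15% of random lists under the planned matching were as high for imprinted and 28.86% for interferon-stimulated genes. At a fold enrichment of at least 5 the percentages under the planned matching were 46.6% for interferon-stimulated and 86.2% for imprinted genes. That limit removes the peaks of every deleted-only imprinted member. Of the deleted-only interferon-stimulated members it leaves only Irf7. At that limit the lists were nearly equal in length, with 19156 and 18380 peaks. In them 2 imprinted members were deleted only and 2 control only, and 3 and 1 interferon-stimulated members. These are mostly other members than those of the pattern, so the limit does not decide on list length. Viral transduction and selection of the deleted culture alone may also raise antiviral genes, and with 0 libraries of transduced cells with Smchd1 undeleted it cannot be told apart from the deletion.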

How the results depend on the processing

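Thinning, peaks anywhere in a gene, protein-coding genes alone, matching on the higher enrichment and left-out parts of X were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the groups share only replicate number 1, and with 1 library per group none could be left out. At −log10 q of at least 5 the deleted and control lists held 46432 and 35955 peaks, 19196 and 6905 of them list-only, X made up 1.38% and 1.21%, and the clusters held 98 and 62. At a fold enrichment of at least 5 they held 19156 and 18380 peaks, 5152 and 3499 list-only, X made up 1.32% of deleted peaks, 21.2% of control X peaks were control-only, 1284 genes and 11 list members were deleted only, and the clusters held 40 and 32. In lists of equal length 24377 deleted peaks were list-only, X made up 1.26% of deleted peaks, 19.6% of control X peaks were control-only, and 1503 and 785 genes were deleted only and control only. Counting peaks within 1 kb as shared left 29393 and 7568 list-only. These shifts follow in part from fewer peaks entering; the cause was not tested further. The other 62 values stayed within 1.5 times the count or within the 95% interval. Counting each summit moved nothing, as no interval had several. The X ratio stayed above every autosome at −log10 q of at least 5, at a fold of at least 5, in equal lists and after thinning, but over all peaks not without 160 to 180 Mb. Of 79 named genes none changed list; 35 kept their status at a fold of at least 5 and 74 in equal lists. With a window of 2500 bases, or a peak anywhere in the gene, 34 of them had a peak in both lists, and with 500 bases 26 had one in neither. Depth limits weak peaks most: absence from the shallower control list does not show absence of the mark.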

Other observations

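The comparisons with windows in this part were chosen after the data were seen. Ratios of windows were ranked with 5 added to each count. Windows of 1 Mb also ran the other way. At the start of chromosome 9, from 3 to 4 Mb, there were 24 deleted and 42 control peaks, with 2 and 21 list-only, the lowest ratio among the 1516 windows. No region was left out here for repeated sequence, so a loss of acetylation in that window is not claimed. On chromosome 1 from 42 to 43 Mb there were 30 and 43. After the region on X, the highest ratios were on chromosome 5 from 26 to 27 Mb, with 22 deleted and 5 control peaks, and on chromosome 8 from 82 to 83 Mb, with 24 and 6.

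Among imprinted regions the excess was uneven. At Snrpn-Ndn 0 of 372 matched windows reached 36 deleted peaks, at Peg13 1.34% of windows reached 39, and at Kcnq1 90.3% reached 40. Windows of such length overlap one another, so the 372 stand for far fewer separate regions. In lists of equal length the Snrpn-Ndn and Peg13 regions held 26 and 27 deleted peaks, reached by 0.512% and 1.02% of windows. At a fold enrichment of at least 5 they held 6 and 3, reached by 51.3% and 36.4%.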
